A study of Mus musculus with 7 samples.

How the data were processed

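Lymphatic endothelial cells of the mouse ear were profiled by RNA sequencing in 7 libraries, 3 from naive skin and 4 from BPC melanomas. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy Micro kit and libraries were made with the Takara SMART-Seq v4 Ultra Low Input kit, which amplifies full-length cDNA and does not mark the strand. Genes that overlap or lie antisense to each other therefore cannot be told apart. The labels name the sex of each library (naive replicate 1 pooled, 2 female, 3 male; tumour replicates 1 and 2 male, 3 and 4 female), and naive replicate 2 pooled 2 genotypes. A tag in the sample descriptions was read as the sequencing lane: naive replicates 1 and 2 on lane 7, naive replicate 3 and tumour replicate 3 on lane 8, and tumour replicates 1, 2 and 4 on lane 6. How the cells were sorted and how many mice entered a library are not given in the sources used here, so p-values measure the spread between these libraries.

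The authors deposited a table of raw counts per gene and a table of normalized values on a log2 scale. Per the submitters' processing notes, Trimmomatic 0.38 and the mm10 build were used. The aligner, the counting tool, the gene annotation and the normalization method are not given in the sources used here. The unit of the count table was read from its values, whole numbers that sum to 52940832 to 63032175 per library. The values the authors deposited as normalized were on a log2 scale already and were used as they stood in 1 alternative only. Among genes with a mean count over 50, their SD across libraries was a median 0.658 times that of log2 counts, and among genes with a mean of 5 to 50 it was 0.0275 times.

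The count table held 26608 entries. In 25 of them a spreadsheet had turned the symbol into a date, and these, with 0.174% to 0.236% of the counts per library, were kept out of the library sizes and tests. Counts were found for 17261 genes. Older symbols in the table were matched to the newer names of the lists (Emr1 for Adgre1, for example). The 13 mitochondrially encoded genes of a fixed list were not analysed here. Ccdc115 alone took 6.68% to 16.5% of the counts of a library. Its 7 counts were all multiples of 1024, as for no other gene of the 13646 with a count over 100, and a fit without it is among the alternatives. Positions come from the GENCODE M21 annotation of GRCm38, the same assembly as mm10. At these depths a floor of 3 counts corresponds to 0.0479 to 0.0521 CPM in a library.

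Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr on the 2 groups, which left 13453, and libraries were scaled by TMM (factors 0.924 to 1.13). Dispersions and quasi-likelihood fits were robust (estimateDisp, glmQLFit), the groups were compared with glmQLFTest, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. The common biological coefficient of variation was 0.749. CPM are counts per 1000000 of the TMM-adjusted library size, and each mean has its SD. The SE of a log2 fold change is its size divided by the square root of the F statistic. For genes with 1 to 9 counts over the naive libraries, the ratio of summed counts is given with an exact 95% interval from the binomial share, and for a gene at 0 the fold against 3 counts per library. Medians of the lists were the same with such genes at their bound.

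The samples, the main test, the 32 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 10 higher and 10 lower genes with the largest change among those past the threshold with mean log2 CPM of at least 4 and no overlap of the groups (passing over gene models, pseudogenes, Xist and Y-linked genes), 13 genes named in advance, 1 of which is not reported here, and from each list the 4 members with the smallest p, or where no member passed the 2 with the highest mean CPM. Lists covered the studied cell (lymphatic identity, collecting vessels, flow, angiogenic signals, junctions, adhesion, chemokines, T cell inhibition, interferon, MHC classes I and II, NF-kB, cell cycle, hypoxia, oxidative phosphorylation, fatty acids, TGF-beta, basement membrane, Notch, unfolded protein response, immediate early and mitochondrial genes) and markers of other cells (blood endothelium, melanocytes, myeloid cells, lymphocytes, fibroblasts, mural cells, keratinocytes, muscle and cartilage, Schwann cells and adipocytes, erythroid cells). The 29 lists with at least 3 tested members were tested as sets with limma's camera (preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the lists. The lists overlap, and Dll4, Notch1, Jam2 and Selp are among the genes that stand in more than 1.

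Alternatives were DESeq2, RLE and upper-quartile factors, no filter and a filter of 5 CPM in 3 libraries, limma-voom with quality weights, limma on the deposited log2 values, the replicate number, lane or sex as a term, glmTreat against a fold of 1.5, no robust estimation, leaving out marker and sex-linked genes, and leaving out each library. Lists were also tested with camera's estimated correlation, with fry and by the median of the members. Chosen after seeing the data were the fits without Ccdc115, with a fibroblast marker score as a term and with the date-named entries kept. Sexes were compared within tumours in a fit of all 7 libraries (as an alternative, of the 4 tumour libraries only) and as an interaction over 6.

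The tests were tried on counts simulated for the 13453 genes of the tumour and naive comparison, with 200 genes changed. edgeR recovered 9 of 50 genes changed 2-fold, 27 of 50 changed 4-fold, 34 of 50 changed 8-fold and 38 of 50 changed 16-fold, and called 6 of 13253 unchanged genes. DESeq2 recovered 12, 33, 38 and 42 of 50 and called 72 of the 13253 unchanged genes. camera called 2 of 2 lists moved 2-fold and 0 of 20 unmoved lists. The genes were simulated independently of each other, so this trial does not show how often camera calls unmoved lists of correlated genes. In the data the estimated correlation within a list reached 0.649, for the fibroblast markers.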

Results

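The data were RNA sequencing counts per gene from lymphatic endothelial cells, the cells that line lymphatic vessels, of the mouse ear. There were 3 libraries from naive ear skin and 4 from BPC melanomas of the ear, which are tumours of mice with the Braf CA allele that carried Cre. Total counts were 59735153 to 63032175 in the naive libraries and 52940832 to 62947508 in the tumour libraries. Between 13441 and 14670 genes had a count in each library. Across genes, the correlation of log2 CPM (counts scaled to the library size) was 0.869 to 0.889 between naive libraries, 0.823 to 0.845 between tumour libraries and 0.766 to 0.839 between a naive and a tumour library. The first principal component held 31.5% of the variance and separated the groups, and the second held 16.8%. The counts of Xist and of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y matched the labelled sex in all 7 libraries. Xist had at least 1591 counts in the female and pooled libraries and at most 2 in the male libraries.

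The comparison of tumour with naive skin asked how the transcripts of lymphatic endothelial cells differed inside a melanoma. The tumour libraries had more RNA of the receptor gene Nrp1, the secreted pattern recognition gene Ptx3, the growth factor gene Pgf and the immune ligand gene Cd276. Genes of cell division, basement membrane and matrix remodelling stood higher as groups. Immediate early genes, genes of Notch signalling such as the ligand gene Dll4, and genes that respond to flow stood lower. Each of these group calls came from camera with a preset correlation between genes, and with an estimated correlation the smallest adjusted p of a list was 0.305. Of 16 genes of lymphatic endothelial identity, 1 passed the test, Sox18, which was higher in tumour. Prox1, Flt4, Pecam1 and the others did not pass. Markers of fibroblasts, myeloid cells, melanocytes and keratinocytes were also higher as groups in the tumour libraries, most of all in tumour replicate 4 for the fibroblast markers.

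Of 13453 genes tested, 121 were higher and 108 were lower in tumour (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With upper-quartile scaling the split was 156 higher and 92 lower, and with limma-voom it was 99 higher and 170 lower. The fold was above 2 for 105 of the higher and 78 of the lower genes. The CPM of the groups did not overlap for any of the 229 changed genes, and for 18.0% of all tested genes, against 5.71% by chance. The total fell to 7 genes without naive replicate 1, 33 without naive replicate 2, 25 without naive replicate 3, 127 without tumour replicate 3 and 102 without tumour replicate 4, and it was 164 to 171 without either of the other tumour replicates; DESeq2 called 1513 genes, and a fit with lane as a term called 0, with 1169 at an unadjusted p under 0.05. Within lane 8, the only sequencing lane with both groups, the 1 tumour library (female) differed from the 1 naive library (male) by a median log2 of 2.16 for the higher genes and -1.15 for the lower genes, beside 2.43 and -1.20 over all 7 libraries. These genes were called with both libraries included and without overlap of the groups. Their direction within lane 8 was therefore fixed in advance, and these values do not test the lane.

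The strongest higher genes by fold, among well expressed ones, were Ecel1, Nrp1, Cd83, Cdh11, Mfap5, C1s, Gpm6b, Ptx3, Col5a2 and Lyz2. Ptx3 rose from 18.8 ± 4.31 CPM (SD, n = 3) in naive skin to 230 ± 30.7 CPM (SD, n = 4) in tumour, a log2 fold change of 3.62 (SE 0.22, adjusted p = 0.000562), and lies on chromosome 3 from 66219910 to 66225805 in GRCm38. Nrp1, which encodes a co-receptor for semaphorins and vascular growth factors (chromosome 8, 128358604 to 128503363), had 5 counts in all over the naive libraries and 28.7 ± 2.98 CPM (SD, n = 4) in tumour. The ratio of its summed counts was 995, with a 95% counting interval of 426 to 3067 (adjusted p = 0.000322), and 1659 without naive replicate 3. Ecel1, an endopeptidase gene (chromosome 1, 87147655 to 87156521), had 2 naive counts and 73.4 ± 50.6 CPM (SD, n = 4) in tumour, a ratio of 6313 with an interval of 1747 to 52131 (adjusted p = 0.00468), and 4197 without naive replicate 1. Such intervals cover counting error only, since reads amplified without molecular identifiers are not independent molecules. Cd83, known from activated dendritic cells, was at 0.0752 ± 0.116 CPM (SD, n = 3) in naive skin and 41.4 ± 20.9 CPM (SD, n = 4) in tumour. Its log2 fold change was 9.07, and 11.92 without naive replicate 2. Gpm6b, a membrane proteolipid gene, had a log2 fold change of 4.29 (SE 0.62, adjusted p = 0.0186).

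The remaining genes of that set are known from fibroblasts or myeloid cells. Mfap5, a microfibril gene, had a log2 fold change of 5.32 (SE 0.96, adjusted p = 0.036), and 4.50 without tumour replicate 4 (adjusted p = 0.055). For C1s, a complement protease gene whose symbol stands for 2 near-identical copies in newer annotations, the values were 4.43 and, without tumour replicate 4, 3.80 (adjusted p = 0.0483 and 0.0821). The cadherin gene Cdh11 had 6.21 and, without that library, 5.61, the collagen gene Col5a2 had 3.29 and 2.67, and the lysozyme gene Lyz2 had 3.17 and 2.37. The highest tumour value was 12.2 times the lowest for Mfap5, 10.3 times for C1s, 8.89 times for Cdh11, 4.92 times for Lyz2 and 4.74 times for Col5a2. In the first part of the set it was 6.16 times for Ecel1, 4.08 times for Gpm6b, 3.40 times for Cd83, 1.37 times for Ptx3 and 1.27 times for Nrp1.

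**Figure D1:**
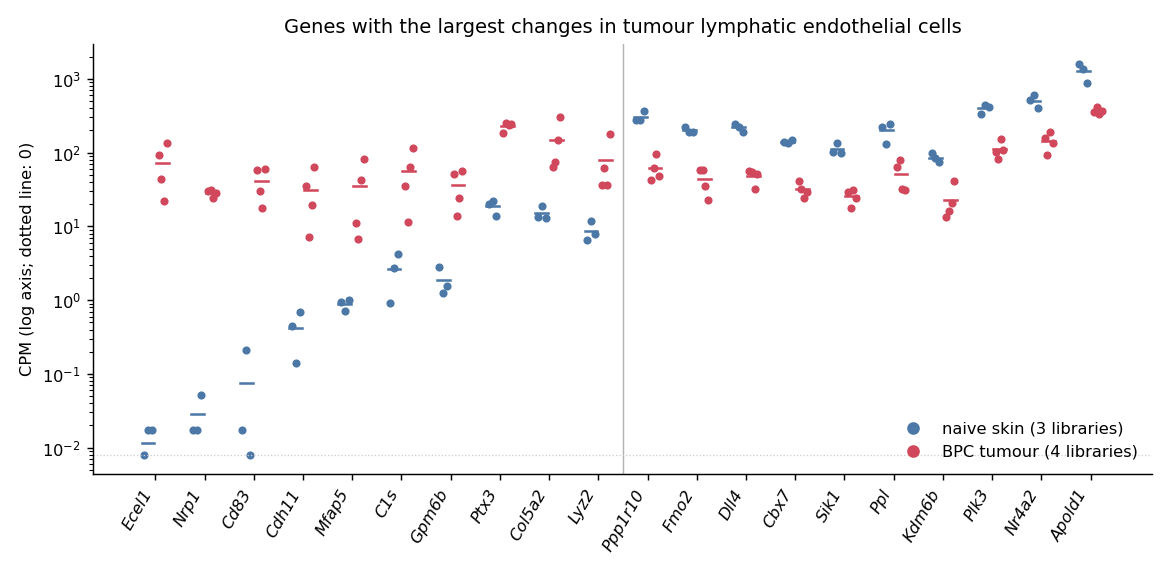
CPM on a log axis of the 10 higher and the 10 lower genes with the largest changes, with a point per library and a bar at the group mean (3 naive, blue; 4 tumour, red; the dotted line stands for 0). No overlap of the groups was a condition for choosing these genes. Nrp1 and Ptx3 vary little between tumour libraries, by 1.27 and 1.37 times.

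The strongest lower genes were Ppp1r10, Fmo2, Dll4, Cbx7, Sik1, Ppl, Kdm6b, Plk3, Nr4a2 and Apold1, with log2 fold changes of -2.31 to -1.80. Dll4, a Notch ligand gene on chromosome 2 (119325784 to 119335962), fell from 220 ± 28.8 CPM (SD, n = 3) to 48.4 ± 11.2 CPM (SD, n = 4), a log2 fold change of -2.18 (SE 0.21, adjusted p = 0.00696). Cbx7, a Polycomb gene, fell from 139 ± 6.27 (SD, n = 3) to 31.7 ± 7.16 CPM (SD, n = 4), with an adjusted p of 0.00525. Ppp1r10, which encodes a regulatory subunit of protein phosphatase PP1, had a log2 fold change of -2.31 (SE 0.28, adjusted p = 0.0112). The orphan nuclear receptor gene Nr4a2 fell from 508 ± 99.7 (SD, n = 3) to 144 ± 41.6 CPM (SD, n = 4), and Apold1, an endothelial early response gene, from 1276 ± 379 (SD, n = 3) to 365 ± 35.6 CPM (SD, n = 4). The kinase genes Sik1 and Plk3 had log2 fold changes of -2.12 and -1.84, the histone demethylase gene Kdm6b -1.89, the flavin monooxygenase gene Fmo2 -2.20 and the plakin gene Ppl -1.94. Of all 229 changed genes, 7 kept the call in each of the 7 fits that left out a library, namely Bche, Cbx7, Ecel1, Emp2, Nrp1, Pgf and Ptx3; Bche and Emp2 were singled out after their values were seen. Of the 53 named genes that passed, 5 kept the call without naive replicate 1, 13 without naive replicate 2, 11 without naive replicate 3, 33 without tumour replicate 3, 30 without tumour replicate 4 and 41 without either of the other tumour replicates.

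Immediate early and dissociation stress genes were lower as a group in tumour. Of 22 measured members, 7 fell, 0 rose and 15 did not pass (15 fell and 2, Hspa1a and Hspa1b, rose when adjusted over the list alone), and the camera test gave an adjusted p of 2.9e-07. With an estimated correlation between genes the adjusted p was 0.305. Junb, an AP-1 transcription factor gene on chromosome 8 (84974484 to 84978718), fell from 13155 ± 1105 CPM (SD, n = 3) to 4230 ± 969 CPM (SD, n = 4), a log2 fold change of -1.64 (adjusted p = 0.01). Ier2, Ier3 and the heat shock co-chaperone gene Dnajb1 fell by 1.44, 1.27 and 1.08 on the log2 scale. The median log2 difference of the list was -0.19 within lane 8 and -0.89 over all 7 libraries, and with lane as a term the list's adjusted p was 0.208.

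Notch signalling genes and flow response genes were lower as well. In the Notch list 3 of 14 members fell and 0 rose (5 fell when adjusted over the list alone), with an adjusted p of 0.00196 by camera, and 0.305 with an estimated correlation. These were Dll4, the feedback gene Nrarp (log2 fold change -1.38, adjusted p = 0.0299) and the receptor gene Notch1, which fell from 245 ± 56.1 (SD, n = 3) to 113 ± 21.8 CPM (SD, n = 4; adjusted p = 0.0385). In the flow list 2 of 11 members fell, Klf4 and Notch1, and 0 rose (4 fell and 1, Cyp1b1, rose when adjusted over the list alone). The flow list's median log2 fold change was -0.58 and its mean -0.06, with Cyp1b1 at 4.77. Its members Notch1, Hes1 and Hey1 also stand in the Notch list, so the calls of these lists are not independent. Klf4, a transcription factor gene induced by shear stress, fell from 740 ± 61.3 (SD, n = 3) to 349 ± 71.7 CPM (SD, n = 4; adjusted p = 0.0219). The flow list had an adjusted p of 0.0237 by camera, 0.305 with an estimated correlation, 0.0518 without naive replicate 3, 0.0691 without tumour replicate 2 and 0.0528 with lane as a term. Within lane 8 the medians were -0.66 for the Notch list and -0.68 for the flow list, beside -0.77 and -0.60 over all 7 libraries.

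**Figure D2:**
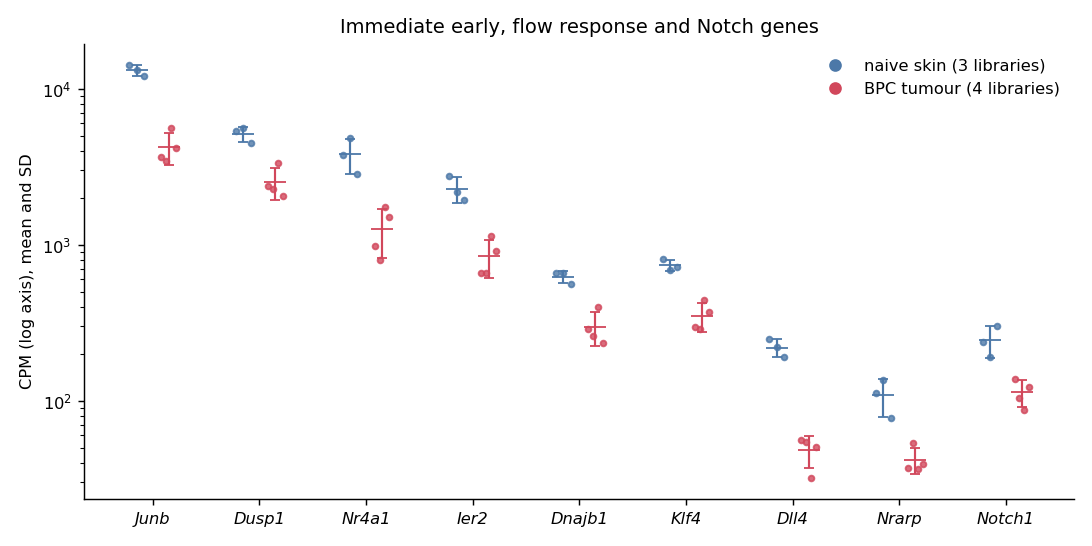
CPM on a log axis of lower genes of the immediate early, flow response and Notch lists, with a point per library and bars for the mean and SD (3 naive, blue; 4 tumour, red). Every tumour library lies below every naive library for each gene, as for Junb with means of 13155 and 4230 CPM.

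Cell cycle genes were higher as a group in tumour. Of 31 measured members 3 rose, 0 fell and 28 did not pass (10 rose and 1, Rrm1, fell when adjusted over the list alone), with an adjusted p of 3.86e-06 by camera and 0.305 with an estimated correlation. The proliferation marker gene Mki67 rose from 6.20 ± 1.06 (SD, n = 3) to 36.2 ± 11.8 CPM (SD, n = 4; adjusted p = 0.0149), and the mitotic genes Ccnb2 and Kif20a had log2 fold changes of 3.02 and 2.38. The median log2 difference of the list was 0.60 within lane 8 and 2.41 over all 7 libraries, and with lane as a term the adjusted p was 0.189.

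Basement membrane and matrix remodelling genes were higher in part. Of 27 members 7 rose, 2 fell and 18 did not pass (14 rose and 3 fell when adjusted over the list alone; adjusted p = 0.00196 by camera, 0.442 with an estimated correlation, 0.208 with lane as a term and 0.45 with the fibroblast marker score as a term). Nid1, a basement membrane linker gene, rose from 179 ± 37.1 (SD, n = 3) to 361 ± 22.3 CPM (SD, n = 4; adjusted p = 0.0219), and the matricellular gene Sparc from 30.4 ± 4.86 (SD, n = 3) to 229 ± 139 CPM (SD, n = 4; adjusted p = 0.0217). The membrane metalloprotease gene Mmp14 had a log2 fold change of 1.09, and Mmp2, Col15a1, Thbs1 and Serpinh1 rose too. Adamts1, a secreted metalloprotease gene, fell from 1016 ± 207 (SD, n = 3) to 447 ± 76.1 CPM (SD, n = 4), and the protease inhibitor gene Timp3 fell as well. The list's median was 1.07 within lane 8 and 1.03 over all 7 libraries. Fibroblasts also express many of these genes, and the fibroblast markers were higher in the same libraries.

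Lymphangiogenic and angiogenic signalling genes were higher as a group, with 3 of 15 members up, 1 down and 11 not past the test (6 up and 2, Dll4 and Kdr, down when adjusted over the list alone). The camera test gave an adjusted p of 0.022, against 0.305 with an estimated correlation, 0.0642 without tumour replicate 1, 0.0681 with limma-voom, 0.0921 with lane as a term and 0.408 with the fibroblast marker score as a term. Pgf, which encodes placental growth factor (chromosome 12, 85166635 to 85177790), rose from 36.8 ± 2.16 (SD, n = 3) to 203 ± 49.6 CPM (SD, n = 4; adjusted p = 0.00468). Nrp1 and Igf1 were the other higher members and Dll4 the lower one. Igf1 had a log2 fold change of 3.10 (adjusted p = 0.0426) and 2.45 without tumour replicate 4 (adjusted p = 0.0512). Over the tumour libraries Igf1 rose with the fibroblast marker score (log2 slope 0.615). The list's median was 0.53 within lane 8 and 0.64 over all 7 libraries.

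T cell inhibition genes gave a call that rested on few members. The camera test gave an adjusted p of 0.0363, with 0.305 for an estimated correlation, 0.111 without naive replicate 3 and 0.0765 without tumour replicate 2, and 1 of 15 members rose (3 when adjusted over the list alone). That member was Cd276, which encodes the immune ligand B7-H3 and rose from 9.57 ± 0.226 (SD, n = 3) to 37.1 ± 4.64 CPM (SD, n = 4; adjusted p = 0.0112). Cd274, which encodes PD-L1, was at 4.60 ± 4.52 CPM (SD, n = 3) in naive skin and 9.13 ± 7.29 CPM (SD, n = 4) in tumour and did not pass (adjusted p = 0.819). The median of the list was 0.59 within lane 8 and 0.28 over all 7 libraries.

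**Figure D3:**
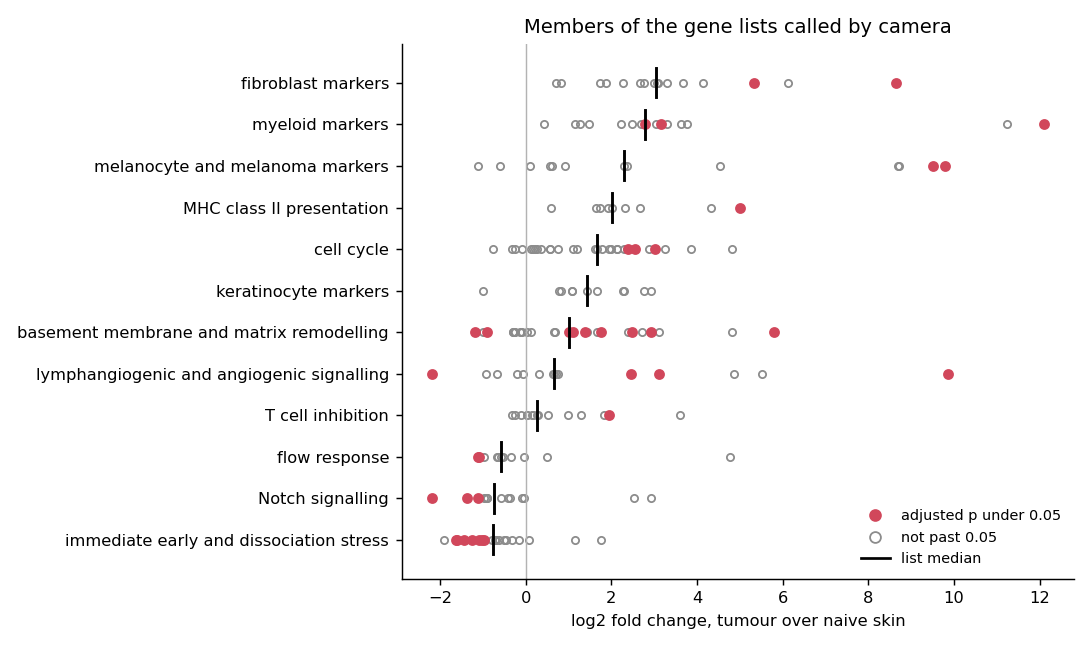
Log2 fold change of each measured member of the 12 lists called by camera (filled red, adjusted p under 0.05; open grey, not past it; black bar, list median). The medians run from 3.03 for fibroblast markers to -0.76 for immediate early and dissociation stress genes, and most members of each list did not pass on their own. Fitted values of genes with few naive counts, such as Nrp1 at 9.86, are not bounds.

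Markers of other cells were higher in the tumour libraries. Of 16 fibroblast markers 2 rose, Pdgfra and Mfap5, and 0 fell (11 rose when adjusted over the list alone; adjusted p = 1.84e-07 by camera and 0.32 with an estimated correlation). Col1a1 was at 346 ± 185 CPM (SD, n = 3) in naive skin and 2914 ± 3220 CPM (SD, n = 4) in tumour, with 7626 CPM in tumour replicate 4 and 665 to 2317 CPM in the other tumour libraries (adjusted p = 0.123). Pdgfra rose from 0.0634 ± 0.0266 (SD, n = 3) to 26.0 ± 23.6 CPM (SD, n = 4; log2 fold change 8.64, and 7.85 without tumour replicate 4), and 14 of the 16 markers were highest in tumour replicate 4. Of 15 myeloid markers 3 rose, Emr1, C1qc and Lyz2, and 0 fell (9 rose when adjusted over the list alone; adjusted p = 9.74e-09 by camera and 0.305 with an estimated correlation). Emr1, the older symbol of the macrophage gene Adgre1, had 0 naive counts and 9.18 ± 8.23 CPM (SD, n = 4) in tumour, at least 177-fold higher with 3 counts per library as the floor (adjusted p = 0.0354), and at least 106-fold without tumour replicate 4 (adjusted p = 0.0839). Lyz2 stood at 8.70 ± 2.72 (SD, n = 3) and 78.3 ± 68.1 CPM (SD, n = 4), and the complement gene C1qc at 6.18 ± 1.08 (SD, n = 3) and 42.4 ± 23.3 CPM (SD, n = 4).

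Of 13 melanocyte and melanoma markers 2 rose, Dct and Sox10, and 0 fell (6 rose when adjusted over the list alone; adjusted p = 0.00473 by camera, 0.32 with an estimated correlation, 0.0528 with lane as a term and 0.0554 with limma-voom). Dct, a pigment enzyme gene, had 5 naive counts and 22.5 ± 19.7 CPM (SD, n = 4) in tumour, a ratio of 778 with an interval of 333 to 2396 (adjusted p = 0.0227). Without naive replicate 1 Dct was at least 434-fold higher, with 3 counts per library as the floor (adjusted p = 0.081), and without tumour replicate 4 the ratio was 473 (adjusted p = 0.058). Sox10, a neural crest transcription factor gene, had 1 naive count and 6.94 ± 4.85 CPM (SD, n = 4) in tumour, a ratio of 1200 with an interval of 215 to 47434 (adjusted p = 0.0321), and was at least 133-fold higher without naive replicate 1 (adjusted p = 0.107). Of 11 keratinocyte markers 0 passed (1, Krt79, rose when adjusted over the list alone), while the list had an adjusted p of 0.00196 by camera and 0.319 with an estimated correlation. The keratin genes Krt14 and Krt10 were at 28.1 ± 11.8 and 23.9 ± 24.1 CPM in tumour (SD, n = 4), beside 13.3 ± 10.6 and 3.17 ± 4.29 CPM in naive skin (SD, n = 3). Of 9 genes of MHC class II presentation 1 rose, the protease gene Ctss, from 0.823 ± 0.172 (SD, n = 3) to 26.6 ± 18.9 CPM (SD, n = 4; adjusted p = 0.0131; log2 fold change 5.01, and 4.41 without tumour replicate 4), and that list had an adjusted p of 0.00234 by camera, 0.393 with an estimated correlation and 0.0528 with lane as a term. Ctss and other members of that list are also abundant in myeloid cells. The medians within lane 8 were 2.48 for fibroblast, 1.58 for myeloid, 3.16 for melanocyte, 1.84 for keratinocyte and 0.97 for MHC class II genes, beside 2.45, 2.87, 1.79, 2.36 and 2.40 over all 7 libraries.

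**Figure D4:**
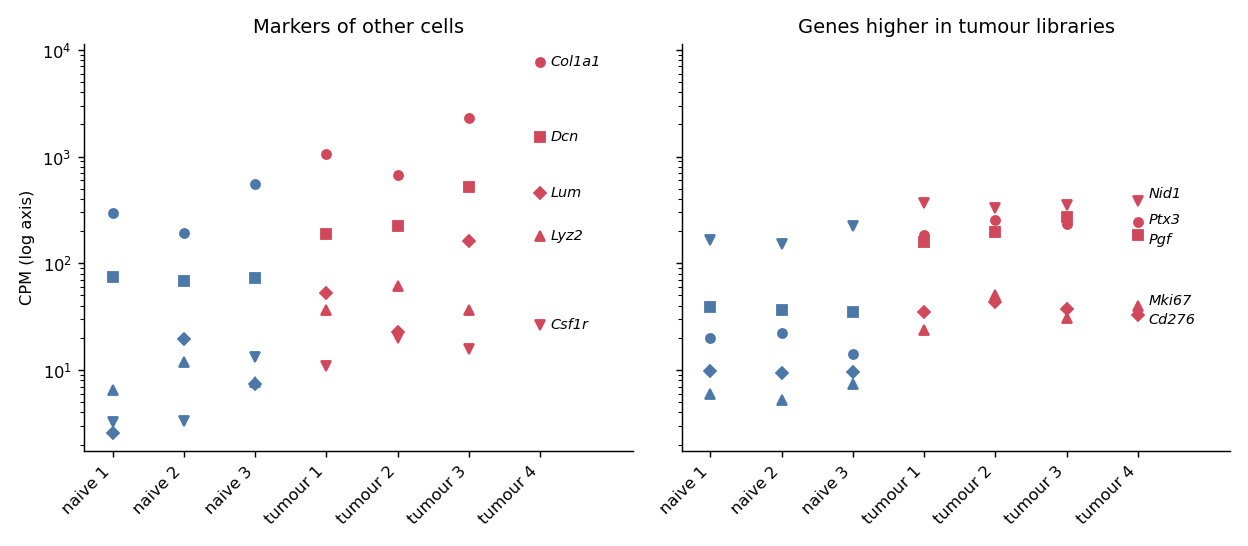
CPM on a log axis in each library of markers of fibroblasts and myeloid cells (left) and of genes higher in the tumour libraries (right), with a point per library (naive, blue; tumour, red). Col1a1 reaches 7626 CPM in tumour replicate 4, while Ptx3 and Cd276 differ by 1.37 and 1.33 times between the lowest and highest tumour library.

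Genes of lymphatic endothelial identity were not called as a group in 1 direction (adjusted p = 0.724 by camera). fry's mixed test, which asks for change either way, gave the list an adjusted p of 0.000601. Sox18, a transcription factor gene of lymphatic development, was the 1 member of 16 that rose, from 70.9 ± 14.5 (SD, n = 3) to 134 ± 7.55 CPM (SD, n = 4; adjusted p = 0.0412). Prox1, the master transcription factor gene of the lineage, stood at 662 ± 125 (SD, n = 3) and 484 ± 131 CPM (SD, n = 4; adjusted p = 0.358), and the hyaluronan receptor gene Lyve1 at 1950 ± 132 (SD, n = 3) and 2591 ± 442 CPM (SD, n = 4; adjusted p = 0.223). Flt4, Pdpn, Pecam1 and Cdh5 had log2 fold changes of -0.07, 0.26, -0.15 and 0.15 and did not pass; the sign for Flt4 turned under upper-quartile scaling (0.00416). The chemokine gene Ccl21a stood at 0.26, and its reads may be shared with near-identical copies. In the list of collecting vessel and valve genes 1 of 12 rose, the water channel gene Aqp1, from 259 ± 84.6 (SD, n = 3) to 630 ± 93.9 CPM (SD, n = 4; adjusted p = 0.0354); the list's median was -0.21, its mean 0.01 and its camera adjusted p 0.727. Among 18 blood endothelial markers Selp rose and Podxl and Efnb2 fell (log2 fold changes 2.63, -0.66 and -1.01), with an adjusted p of 0.724 for the list.

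Genes of leukocyte adhesion and transmigration held 3 higher members of 17, and the list had an adjusted p of 0.0983 by camera. These were the P-selectin gene Selp (5.92 ± 2.11, SD, n = 3, to 36.5 ± 11.1 CPM, SD, n = 4; adjusted p = 0.0219), the mannose receptor gene Mrc1 (log2 fold change 1.38, adjusted p = 0.0217) and the junction gene Jam2, with 1 naive count and 8.71 ± 7.80 CPM (SD, n = 4) in tumour. For Jam2 the ratio was 1495 with an interval of 268 to 59074 (adjusted p = 0.0289), 994 without naive replicate 1 and 891 without tumour replicate 4 (adjusted p = 0.0764), and without naive replicate 2 Jam2 was at least 169-fold higher, with 3 counts per library as the floor (adjusted p = 0.0924). Icam1 stood at 1315 ± 175 (SD, n = 3) and 591 ± 216 CPM (SD, n = 4) and did not pass (adjusted p = 0.0904), and Vcam1 was at 1.18 ± 2.03 (SD, n = 3) and 0.739 ± 0.834 CPM (SD, n = 4), with the direction turning between settings. Jam2 was also the 1 member of 15 endothelial junction genes that rose (adjusted p = 0.901 for the list). Of 18 chemokine and trafficking genes 0 passed (adjusted p = 0.724); Cxcl12 stood at 37.0 ± 16.6 (SD, n = 3) and 136 ± 62.4 CPM (SD, n = 4; adjusted p = 0.0693) and the sphingosine transporter gene Spns2 at a log2 fold change of -0.41.

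Lists of immune, metabolic and stress responses gave few calls. No member passed among 28 interferon response genes (adjusted p = 0.807 for the list), 17 genes of MHC class I presentation (0.192), 18 of the NF-kB and TNF response (0.204), 24 of the hypoxia response (0.733) and 23 of oxidative phosphorylation (0.109). Irf1 and Gbp7 had log2 fold changes of -0.67 and 0.11, Pdia3 and H2-D1 0.70 and 0.04, Nfkbia -0.23, Aldoa and Ldha 0.09 and 0.23, and Atp5a1 and Sdha 0.10 and -0.07. H2-D1 shares reads with similar class I genes and is uncertain, and the sign for Sdha turned under upper-quartile scaling (0.00273). In fatty acid handling 1 of 18 genes fell, the acyl-CoA synthetase gene Acsl1 (log2 fold change -1.37, adjusted p = 0.0412; 0.863 for the list). In TGF-beta and mesenchymal transition 1 of 25 rose, the repressor gene Zeb2, with 7 naive counts, a ratio of 273 and an interval of 132 to 679 (adjusted p = 0.0125; 0.87 for the list). Zeb2 also rose with the fibroblast marker score over the tumour libraries (log2 slope 0.589). In the unfolded protein response 1 of 17 rose, the disulfide isomerase gene Pdia6 (log2 fold change 0.80, adjusted p = 0.0245; 0.863 for the list). Braf, which has an engineered allele in this model, had a log2 fold change of -0.46 and did not pass (adjusted p = 0.511), and counts per gene do not tell alleles apart.

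Further markers of other cells did not pass. Of 4 lymphocyte markers 0 passed, with Thy1 and Lck at log2 fold changes of 0.18 and 1.10; the list's median was -0.20, its mean -0.09 and its camera direction upward (adjusted p = 0.863). Of 6 mural and smooth muscle markers 0 passed, with Mcam at 0.50 and Pdgfrb at 3.18 (adjusted p = 0.149 for the list), and of 6 Schwann and adipocyte markers 0 passed, with Pmp22 at -0.48 and Cnp at 0.38 (adjusted p = 0.694 for the list). Skeletal muscle and cartilage markers had 2 tested members, Comp (-0.78) and Mylpf (-0.42), and erythroid markers had 1, Hba-a2 (1.36), and 0 of these passed.

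The libraries also allowed a comparison of sexes within tumours, with 2 male and 2 female libraries. Of 14381 genes tested, 0 passed with edgeR's quasi-likelihood test, 1050 had an unadjusted p under 0.05, and DESeq2 called 388, of which 5 were Xist and Y-linked genes. Xist, at 53.7 CPM in female and 0.00828 CPM in male tumours, had an adjusted p of 0.52, so the test missed a difference that the labels give. The smallest adjusted p was that of Egr2 (0.0608), an immediate early gene at 104 CPM in female and 22.5 CPM in male tumours. In a fit of the 4 tumour libraries only, 0 genes passed, Xist, Ddx3y and Eif2s3y had the smallest adjusted p (0.106), and Egr2 had 0.345. The tumour effect by sex, tested as an interaction over 6 libraries with 1 naive library per sex, gave 0 of 15706 genes, 557 at an unadjusted p under 0.05, and 169 with DESeq2, and its smallest adjusted p was 0.837.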

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

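The tests of fibroblast RNA, melanoma RNA, dilution and lane were chosen after the results were seen, and the counts over other splits of the libraries were planned.

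The tumour effect was compared with other splits of the 7 libraries into 3 and 4. Only 1 of the 35 splits, the real split, gave as many changed genes (229, against at most 3 in another split). This is the smallest share that 35 splits allow, which makes a random split unlikely but does not exclude it. The other splits mix the groups, so their low counts would follow from any difference between the groups, that of lane included. For gene lists 1 of 35 splits, again the real one, gave as many calls (12), but the highest other split, which moves tumour replicate 2 to the naive libraries and so keeps most of the contrast of the groups, gave 11. That split does not follow a lane. Nearly all other splits called at least 1 list, although most of them called 0 genes. Only the split that set naive replicate 2 and tumour replicates 2 and 3 apart called 0 lists. List calls of camera with the preset correlation thus arose in most mixed groupings of these libraries.

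Markers of fibroblasts, myeloid cells and melanocytes were higher in the tumour libraries; none of these markers stands in another list, and 12 of 16, 9 of 15 and 6 of 13 had a mean of at least 1 CPM in naive skin too. The 16 fibroblast markers ordered the 4 tumour libraries alike (mean pairwise Spearman correlation 0.738), and 14 were highest in tumour replicate 4, where Col1a1 reached 7626 CPM and Dcn 1512 CPM. RNA or cells of fibroblasts in the isolated material, whose sort is not given in the sources used here, is therefore a candidate source of these transcripts, in amounts that differ between tumours. Ptprc, the gene of CD45, was at 6.32 CPM in tumour replicate 4 and at most 0.0492 CPM elsewhere. Lane cannot be told apart as a contributor, since lane 8, where the median marker difference was 2.48, holds 1 library per group, of different sex, and expression of these genes by the lymphatic endothelium of tumours also stays open and untested.

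Among the 121 higher genes, some varied with the fibroblast markers and most did not. Their slope on the fibroblast marker score over the 4 tumour libraries had a median of 0.103 (quartiles -0.022 and 0.446). A slope near 1 is expected only of genes whose tumour RNA comes from fibroblasts alone. These values argue against such an origin for most of the set. Genes that the endothelium also expresses would have flatter slopes, so a part from fibroblasts is not excluded. The slopes were 0.5 or more for 30 genes, such as C1s, Cdh11, Igf1, Zeb2 and Sparc, which may come from fibroblasts or from other cells that vary alike. Pdgfra and Mfap5 are members of the score, so their slopes of 0.925 and 1.14 are partly built in. The slope does not single out fibroblasts, since the melanocyte and melanoma markers had a median of 0.891. The 15 myeloid markers had a median of only 0.194 (quartiles 0.132 and 0.287), although 1 of them, the macrophage gene Emr1, had 0.901. For the 31 cell cycle genes the median slope on the fibroblast score was -0.0802 (upper quartile 0.151). With 4 libraries, this argues only against fibroblasts with an even share of dividing cells as the sole source of that list. Melanoma cells cannot be told apart as a source of it: the median slope on the melanocyte and melanoma marker score was -0.034, but these markers did not order the tumour libraries alike (mean pairwise Spearman correlation 0.159), and 6 of the 13 had a tumour mean below 2 CPM. A difference between tumour and skin in the endothelium itself remains an open hypothesis for genes such as Nrp1, Ptx3, Pgf, Cd276 and Mki67. A small slope does not single out the endothelium, since the myeloid markers had small slopes too. RNA of myeloid or other cells, other dividing cells, the lane and the handling of the tissue were not excluded. With the fibroblast score as a term only 5 genes were called, but the score itself separates the groups (2.22 to 3.29 in naive and 4.35 to 7.59 in tumour libraries), so this fit removes much of the contrast.

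Immediate early genes were lower in the tumour libraries. Dilution by RNA of other cells would lower the genes of lymphatic endothelial identity as much. These had a median log2 fold change of 0.117 (quartiles -0.225 and 0.297) beside -0.76 for the immediate early list, which argues against dilution as the sole cause. Members of the identity list ran from -0.45 for Prox1 to 0.92 for Sox18, and other cells may express some of them, so a smaller dilution is not excluded. Lane cannot be told apart from the group for this list, because the median difference within lane 8 was only -0.19 with 1 library per group, a male naive and a female tumour library, so that sex and animal differ within this pair too. Dissociation of skin and of tumours may induce these genes to different degrees, which the design confounds with the tissue, and a biological difference between the tissues stays open as well. Handling is confounded with the group for the other lower genes too, such as Nr4a2 and Apold1.

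Among 91 quantities examined over the 4 tumour libraries, 2 had a sample far from the others, where chance gives about 1 in 20. H2-D1 was at 1047 CPM in tumour replicate 1 and 720 to 770 CPM in the other tumour libraries. Nrarp was at 53.4 CPM in tumour replicate 2 and 36.7 to 39.3 CPM in the other tumour libraries. The date-named entries held 0.190% to 0.236% of the counts in the tumour libraries (mean 0.218%) and 0.174% to 0.192% in the naive libraries. Of the genes with no count in any library, 1006 had a value other than 0 among the authors' normalized values.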

How the results depend on the processing

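The alternatives were planned, except the fits without Ccdc115, with the fibroblast score and with date-named entries kept, which were chosen after seeing the data. All 229 changed genes kept their direction in every setting that gave them a value, while the number past the threshold moved widely. The CPM of the groups did not overlap for any of these genes, so leaving out a library could hardly turn a direction. DESeq2 called 1513 genes (947 higher, 566 lower), among them all 229, a filter of 5 CPM in 3 libraries called 359 (190 and 169), and limma-voom 269 (99 and 170). limma on the authors' normalized values called 109 (61 and 48), glmTreat, which asks for more than a fold of 1.5, 50 (35 and 15), sex as a term 12 (6 and 6), the fibroblast score as a term 5 (5 and 0) and lane as a term 0 (0 and 0, with 1169 at an unadjusted p under 0.05). Leaving out each library gave 7 to 171 genes in total, 6 to 105 higher and 1 to 88 lower. The demand for a larger fold lowers the count by construction, and fewer libraries or terms that overlap with the groups leave less information to the test. With lane as a term, the group difference rests on naive replicate 3 and tumour replicate 3 alone. With sex as a term, naive replicate 1 adds nothing to the group difference, since it is the only pooled library. For the other settings the cause was not tested. RLE and upper-quartile factors, no filter, no robust estimation and the fits without marker genes, without Ccdc115 and with date-named entries kept gave 216 to 251 genes; upper-quartile scaling moved the median log2 fold change of all genes from 0.04 to 0.11.

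The labels number replicates in both groups, but tumour and naive libraries of the same number did not deviate together (correlations across genes of -0.0064, -0.0367 and -0.0206), and not every library correlated best with its own number, so the number was not read as pairing. With the replicate number as a block the total was 3 genes (3 higher, Ecel1, Nrp1 and Ptx3, and 0 lower), and the flow, angiogenic signalling, T cell inhibition and melanocyte lists were not called (adjusted p of 0.0602, 0.0553, 0.0875 and 0.068). It changed no other list call.

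The main test called 9 lists higher and 3 lower. With lane as a term 5 and 1 were called (oxidative phosphorylation was new among the 5, and 5 of the 12 calls were kept), without marker genes 5 higher (which removes marker lists by construction), with the fibroblast score 3 higher, with camera's estimated correlation 0 and 0, and by fry 5 higher (leukocyte adhesion was new among the 5, and 7 of the 12 calls were kept); the cause was not tested. Called lists had 242 alternatives that kept the call, 42 that lost it and 0 with a turned direction, and called genes had 737, 472 and 0. In the other direction, oxidative phosphorylation was called in 8 alternatives (adjusted p down to 0.00656, over a range up to 0.806), and mural and smooth muscle markers without a filter (0.0471, against 0.149). The fibroblast score ended the calls of the lists for flow response (0.0983), angiogenic signals (0.408), T cell inhibition (0.0827), MHC class II (0.055), basement membrane (0.45), melanocytes and fibroblasts (both 0.869). fry's mixed test, which asks for change either way, gave an adjusted p of 0.000601 for lymphatic identity and 0.656 for interferon. In the sex comparisons DESeq2 called 388 genes against 0, and 169 against 0 for the tumour effect by sex; the cause was not tested.

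A turn of direction occurred only in results that passed no threshold, 35 for lists and 27 for genes; the cause was not tested. Adjusted p of the lists with a turned direction were as follows. With the fibroblast score they were 0.58 for junctions, TGF-beta and Schwann and adipocyte markers, 0.956 for interferon, lymphocyte and mural markers and 0.816 for blood endothelial markers. Without a filter they were 0.953 for junctions and fatty acids and 0.862 for Schwann and adipocyte markers, and with the filter of 5 CPM 0.849 for TGF-beta and 0.822 for blood endothelial markers. With limma-voom they were 0.934 for junctions and 0.99 for TGF-beta, and with limma on the authors' values 0.736 for junctions and 0.999 for Schwann and adipocyte markers. With sex as a term they were 0.894 for junctions, 0.77 for hypoxia and 0.924 for fatty acids, and with lane 0.693 for NF-kB, 0.787 for fatty acids and 0.332 for the unfolded protein response. Over the fits that left out a library they ranged from 0.825 to 0.986 for junctions, 0.187 to 0.986 for interferon, 0.489 to 0.875 for hypoxia, 0.821 to 0.979 for fatty acids, 0.543 to 0.989 for the unfolded protein response, 0.163 to 0.978 for blood endothelial markers, 0.708 to 0.979 for lymphocyte markers and 0.216 to 0.978 for Schwann and adipocyte markers. The median difference of the lymphocyte markers was -0.42.

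Log2 fold changes of the genes that turned were, with the fibroblast score, -0.0031 for Pdpn, 0.0227 for Pecam1, -0.0334 for Cdh5, -0.233 for Ccl21a, 0.453 for Braf, 0.0365 for Spns2, 0.843 for Mylpf, 0.0407 for Pmp22 and -0.0173 for Cnp. With upper-quartile factors they were 0.0042 for Flt4 and 0.0027 for Sdha. With limma-voom they were 0.228 for Vcam1, -0.174 for Gbp7 and -0.0162 for H2-D1, and with limma on the authors' values -0.0823 for Gbp7. With lane as a term they were 6.25 for Vcam1, -0.225 for Gbp7 and 0.22 for Nfkbia, with sex -0.0693 for Gbp7 and -0.0098 for H2-D1, and with the replicate block 2.59 for Vcam1. Over the fits that left out a library they ranged from -0.208 to 0.164 for Flt4, -1.27 to 6.11 for Vcam1, -0.499 to 0.344 for Gbp7 and -0.0971 to 0.155 for H2-D1. Vcam1 was at 3.53 CPM in naive replicate 2 and at most 1.47 CPM in the other libraries, and its fold has no stable size here.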

Other observations

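Several immediate early genes had larger values in female than in male tumours, and none passed the adjusted test. Egr1 averaged 1499 CPM in the 2 female and 385 CPM in the 2 male tumours (adjusted p = 0.0755 with edgeR's quasi-likelihood test, and 0.345 in a fit of the 4 tumour libraries only), Fos 1049 and 224 CPM (0.0797 and 0.292), Fosb 279 and 48.2 CPM (0.253 and 0.666) and the flow response gene Klf2 134 and 43.7 CPM (0.253 and 0.53), with each gene chosen after its values were seen. Tumours of the same sex did not all share a lane, with both males and 1 female on lane 6 and 1 female on lane 8.

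A part of the higher genes had almost no counts in the naive libraries and clear counts in the tumour libraries. Emr1, Dct and Sox10, markers of macrophages or melanocytes, are among them, so RNA of other cells was not told apart from expression by the endothelium. Of the 121 higher genes, 30 had at most 9 counts over the 3 naive libraries and 11 had 0, while 0 of the 108 lower genes had at most 9 counts over the 4 tumour libraries. Among all tested genes, 7 had at most 9 naive counts and at least 5 CPM in every tumour library, and 0 showed the opposite. Tested genes at 0 counts made up 7.19% in naive replicate 1 and 2.72% to 4.91% in the other libraries.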
